A study of Mus musculus with 6 samples.

How the data were processed

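The series holds RNA-seq of 6 libraries of sorted germinal centre B cells, 3 wildtype and 3 SFR KO. Groups were taken from the genotype in the labels, and replicates were numbered in accession order because the labels give none. Per the submitters' processing notes, STAR 2.5, featureCounts 1.5, DESeq2 1.14.1 and the mouse build GRCm38 were used; the annotation release, the strand setting and any filters are not given in the sources used here. The authors deposited, per gene, read counts normalized to library size as a signal, together with the mean over libraries. The authors also deposited a log2 fold change of KO over wildtype with its standard error, a test statistic as a score, and a p-value with an adjusted p-value for each gene.

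The table lists 55421 genes, of which 24646 had a read. Values of each library were whole multiples of its smallest value, and 100% of values came out whole within a tolerance of 1e-06, so whole reads were recovered by division. The libraries held 33041831, 30413716 and 30354086 reads in wildtype 1, 2 and 3 and 31260196, 28269310 and 33053024 in SFR KO 1, 2 and 3. Pairs of libraries of 1 group differed by far more than sampling noise, with a chi-square per gene of 6.11 or more, so all 6 were used as separate samples. Gene positions, the longest transcript of each gene and its GC content came from GENCODE release M21 on the same build, which matched 99.5% of the genes; 99.8% of tested genes had a GC content.

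The main test was limma 3.58.1 (lmFit, then eBayes with a trend; R 4.3.3) on log2(normalized count + 1), two-sided, with genotype as the factor, for genes with a mean of at least 10 normalized reads over the 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 13562 tested genes were called. Fold changes and their standard errors are on this log2 scale, which understates the change of low genes. For the deleted genes and Capn11, ratios of reads were scaled to library size and given with exact binomial 95% intervals, or against a floor of 3 reads over the group where no read was seen; intervals and floors cover counting error only.

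The text names genes by a rule fixed before the data were examined. It takes the 7 deleted genes, and the 10 higher and 10 lower called genes with the largest log2 change among those with non-overlapping groups and a mean of at least 50 normalized reads, leaving out antibody and T cell receptor segments and unnamed models. It adds up to 4 called members of each gene list, or up to 2 uncalled members as values, and Bcl6, Fas, Cxcr4, Cd83, Myc and Prdm1; 1 further gene of the rule is not reported here. The 36 gene lists, with 555 gene symbols for B cell states, cell processes and other cell types, were fixed at the same time; the deleted genes and a list of sex-linked transcripts were kept out of the tests. The 33 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists. Of the sex-linked list, Ddx3y and Kdm5d had reads in all 6 libraries, at log2 differences of -0.04 ± 0.07 and -0.05 ± 0.09.

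Alternatives were other pseudocounts, filters and scalings, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, limma with sample weights or with a robust prior, and each library left out. For lists they were camera with an estimated correlation and fry, which asks whether a list moves 1 way without setting it against other genes. After the data were seen, 4 alternatives were added. These were removal of each library's trend with GC content (a natural spline with 4 degrees of freedom), the same with transcript length, the first together with an estimated correlation for lists, and a fit with wildtype 1 as the sole wildtype library, whose spread is then assumed to be that of the other group. The steps were tested on simulated counts drawn for the comparison of SFR KO with wildtype over 13414 genes. In these limma recovered 38%, 68%, 82% and 100% of 50 genes each changed by a log2 of 0.4, 0.7, 1 and 2, with 12 false calls. In a simulated shift of the light zone list by a log2 of 0.2, camera called 1 list, the shifted one. Genes were drawn independently of each other. The simulation therefore cannot show how the preset correlation serves lists whose members vary together, such as ribosomal proteins (estimated correlation 0.78).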

Results

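RNA was sequenced from germinal centre B cells, the B cells that mutate and select their antigen receptors in lymphoid follicles after immunisation. The cells came from spleens of C57BL/6 mice with a green fluorescent protein (GFP) reporter. Spleens were taken on day 9 after immunisation with ovalbumin carrying the hapten NP at a ratio of 18, given in alum. GFP-positive cells were sorted, and 3 wildtype libraries were compared with 3 libraries from SFR KO mice, which carry a deletion across SLAM family receptor genes. Each library held between 28269310 and 33053024 reads assigned to genes, as recovered from the normalized values. The labels number the samples individually without stating that each is a separate mouse, so p-values measure the spread between these samples. Bcl6, the germinal centre transcription factor, stood at 15280 ± 685.5 normalized reads in wildtype and 13930 ± 384.8 in SFR KO libraries (mean ± SD, n = 3 each). Its log2 difference was -0.13 ± 0.05 (SE), with a limma adjusted p = 0.245. Fas and Prdm1 also missed the threshold. The log2 difference was -0.06 ± 0.06 for the death receptor gene Fas (adjusted p = 0.698). For Prdm1, the plasma cell regulator, it was 0.42 ± 0.18 (adjusted p = 0.308).

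The first question was whether the deleted genes were lost from the SFR KO libraries. SLAM family receptors are cell surface proteins that mostly bind their own kind on neighbouring cells, and the deletion is described as starting in intron 1 of Cd244 and ending in exon 8 of Slamf6. All 7 genes were lower in SFR KO libraries, and the values of the groups did not overlap for any of them. Slamf7 fell from 5388 ± 2117 normalized reads (SD, n = 3) to 1 read in all 3 SFR KO libraries together, a ratio of 16400 with a 95% exact binomial counting interval of 2940 to 647000. Cd48 and Slamf1 likewise had 1 read each in the SFR KO group, with ratios of 5250 (941 to 207000) and 4520 (811 to 179000). Ly9 and Cd84 had 0 reads in SFR KO libraries and were at least 2920-fold and at least 524-fold lower, against a floor of 3 reads over the group. Slamf6 kept 30 reads, a ratio of 213 (149 to 316). Cd244a was low in wildtype cells at 49.73 ± 28.44 normalized reads and kept 6 reads, a ratio of 25.3 (11.4 to 70.1). The described edges of the deletion lie within Cd244a and Slamf6, so parts of both genes can remain. Where in these genes the remaining reads lie was not tested. Ratios moved with single libraries. The limits of Ly9 and Cd84, with 0 reads in every SFR KO library, fall by construction when an SFR KO library is left out, since the floor of 3 reads then covers fewer libraries. Without SFR KO 3, Slamf7 and Cd48 had 0 reads and were at least 3510-fold and at least 1130-fold lower, the ratio of Slamf1 was 2910 and that of Cd244a 16.3, and the limits of Ly9 and Cd84 were 1880 and 337. Without SFR KO 1, Slamf1 had 0 reads and was at least 997-fold lower, the ratios of Slamf7, Cd48 and Cd244a were 10800, 3470 and 100, and the limits of Ly9 and Cd84 were 1930 and 347. Without wildtype 1 the ratio of Cd244a was 16.8. Limma adjusted p-values ran from 8.66e-08 for Ly9 to 0.0466 for Cd244a. The Cd244a call was lost in 10 of the 18 alternative settings that gave it a value, among them edgeR (adjusted p = 0.0527). It was also lost without wildtype 1 (0.138), wildtype 2 (0.144), wildtype 3 (0.108), SFR KO 2 (0.187) or SFR KO 3 (0.0777).

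**Figure D1:**
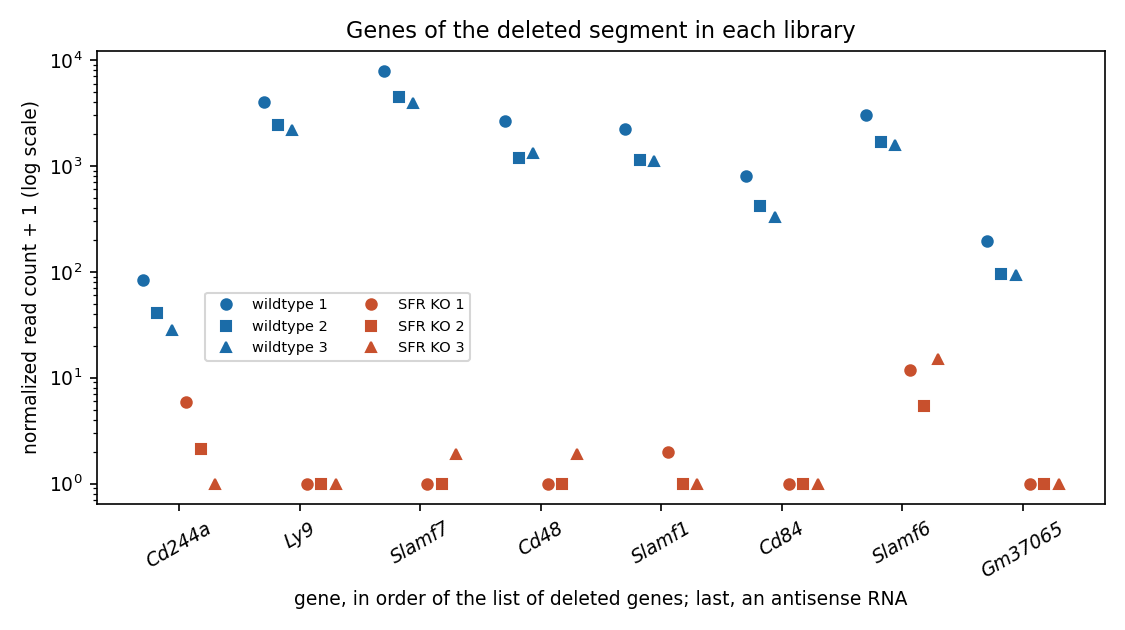
Normalized read count plus 1 (log axis) of the 7 deleted genes and the antisense RNA Gm37065 in each of 6 libraries, 1 point per library. Wildtype libraries (blue) had between 27.4 and 7815.3 normalized reads and SFR KO libraries (red) at most 14, and wildtype 1 was the highest wildtype library for each gene.

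The segment from the start of Cd244a to the end of Slamf6 covers positions 171559193 to 171953170 of chromosome 1 (GRCm38), and 8 genes inside it could be tested. The last of them was Gm37065, a long non-coding RNA on the minus strand that overlaps the start of Slamf6. It had 127 ± 59.03 normalized reads in wildtype and 0 reads in SFR KO libraries, at least 129-fold lower (limma adjusted p = 0.000126). The limit was 85.3 without SFR KO 1 and 83 without SFR KO 3, which follows from the fixed floor over fewer libraries. Cd244a and Ly9 overlap on opposite strands, as do Gm37065 and Slamf6. The strand setting of the read counting is not given in the sources used here, so the values of these overlapping genes are uncertain. Within the wildtype group all 7 genes were higher in wildtype 1 than in wildtype 2 and 3. Slamf7, for example, had 7815.3, 4426 and 3922.7 normalized reads. No listed neighbour of the deletion passed the limma threshold. At the rate of the other genes, 55 of 13525, 0.118 calls would fall among the 29 neighbours, so that 0 calls cannot show them to be unaltered (two-sided Fisher's exact p = 1, which a count of 0 gives in any case). Of these 29 genes, 4 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. The DESeq2 call was Usp21, a deubiquitinase gene, with a limma log2 difference of -0.30 ± 0.07 (limma adjusted p = 0.0915; DESeq2 0.0281), which was also the 1 gene lower when adjusted over the list alone. Without SFR KO 1, limma called 1 of the neighbours. Within 10 Mb of the segment, limma and edgeR called 0 of 159 genes and DESeq2 called 4, and 23 had an unadjusted p under 0.05. Of all 13562 tested genes, DESeq2 called 491 and 2185 had an unadjusted p under 0.05. The counts near the deletion are no excess over these rates.

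The second question was which other genes differed between the genotypes. Outside the segment, 21 genes were higher and 34 lower in SFR KO libraries. Most changes were small, with a median absolute log2 change of 0.42, 14 genes past 1.5-fold and 4 past 2-fold. These 4 were Rsrp1, Ret, Capn11 and the antibody segment Ighv9-1, the last named after its value was seen. Rsrp1, which encodes an arginine and serine rich protein (chromosome 4, 134923592 to 134927671), rose 2.79-fold from 2233 ± 503.4 to 6149 ± 718.1 normalized reads (SD, n = 3; log2 1.48 ± 0.15 SE, limma adjusted p = 0.00526). Clk1 and Clk4, kinases of splicing factors, rose 1.73-fold (log2 0.79 ± 0.08, adjusted p = 0.00488) and 1.58-fold (log2 0.66 ± 0.09, adjusted p = 0.0246). Ctso, a lysosomal cathepsin (chromosome 3, 81932601 to 81956725), rose 1.49-fold, with SFR KO values of 3545 to 3703.2 against wildtype values of 2389.9 to 2439.7 (adjusted p = 0.000878). Alcam, an adhesion molecule, rose 1.62-fold (log2 0.69 ± 0.07, adjusted p = 0.00557). Smad1, a transducer of bone morphogenetic protein signals, rose 1.68-fold and Clec2i, a C-type lectin, 1.59-fold. Eaf2, a transcription elongation factor, rose 1.55-fold, and Cd72, an inhibitory receptor of B cells, 1.41-fold.

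Among the genes that fell, Capn11, a calpain protease gene (chromosome 17, 45630204 to 45659325), had 22.3, 244.1 and 100.6 normalized reads in the wildtype libraries. It had 0 reads in all 3 SFR KO libraries, at least 119-fold lower (limma adjusted p = 0.0153; edgeR 0.0613). This limit was 59.6 without wildtype 2, 78.5 without SFR KO 1 and 76.4 without SFR KO 3. The values without an SFR KO library follow from the fixed floor over fewer libraries. Ret, a receptor tyrosine kinase, fell to 0.373 times its wildtype level (log2 -1.42 ± 0.20, adjusted p = 0.0318), from 375.4 ± 46.76 to 142.3 ± 38.72 normalized reads. Ackr2, a chemokine-scavenging receptor, and Nrep fell to 0.527 and 0.541 times wildtype. Mical3, of the MICAL oxidoreductases, Lpcat1, a phospholipid acyltransferase, Sbk1, a kinase, and Sfn, a 14-3-3 protein, fell to between 0.638 and 0.716 times. Myc, a driver of growth that is induced in selected light zone cells, fell to 0.701 times wildtype (log2 -0.51 ± 0.07, adjusted p = 0.0322). Plcg1, a phospholipase of receptor signalling, fell to 0.703 times. Syk, the kinase next to the B cell receptor, fell from 35330 ± 731.4 to 27400 ± 391 normalized reads (log2 -0.37 ± 0.05, adjusted p = 0.0185).

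**Figure D2:**
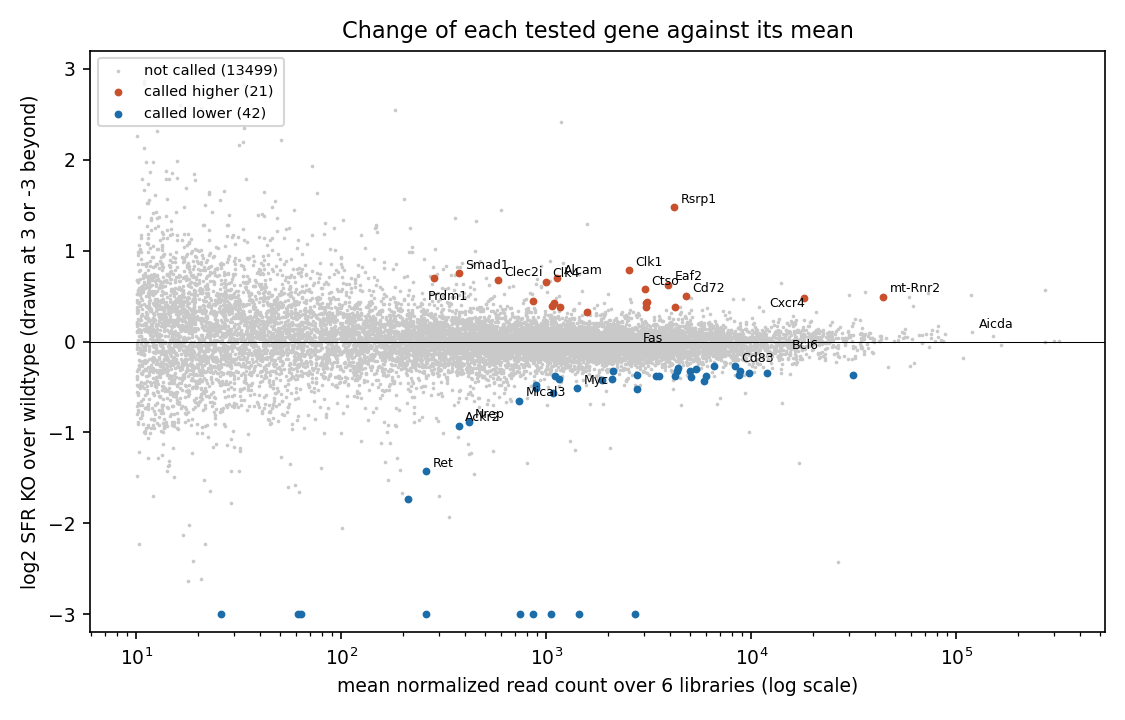
Log2 difference of SFR KO over wildtype (vertical axis) against mean normalized read count over 6 libraries (log axis), 1 point per tested gene; red marks the 21 genes called higher, blue the 42 called lower, and points beyond 3 or -3 are drawn at those values. Most called genes lie within 1 log2 unit of 0, while the deleted genes and Capn11 lie at the lower edge.

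In all, limma called 63 of 13562 tested genes, and 2943 genes (21.7%) had groups that did not overlap, where chance gives 10%. The number of calls changed with 1 library left out, which also leaves fewer samples for the test. It rose to 501 genes without SFR KO 1. It fell to 26 without wildtype 2, 21 without SFR KO 3 and 14 without wildtype 3. Without wildtype 1 it was 13 and without SFR KO 2 it was 11. Of the 55 calls outside the segment, 4 were made in each of those 6 fits: Clk1, Ctso, Alcam and Rsrp1. Another 39 were made in none of those fits but the one without SFR KO 1. On the recovered reads edgeR called 30 genes and DESeq2 491. The authors' deposited table held 497 genes with an adjusted p under 0.05, 185 higher and 312 lower, including 54 of these 55 genes. The called genes also differed in base composition: the median GC content of the longest transcript was 39.3% for the 21 higher genes and 55.8% for the 34 lower genes. It was 49.2% over 8589 protein-coding genes with a mean of at least 200 normalized reads. Across those genes, which are not independent replicates, the log2 difference fell with GC content (Spearman's rho -0.409). With the trend of each library removed, 9 of the 55 genes still passed the threshold, among them Clk1, Ctso, Alcam, Rsrp1, Cd72, Smad1 and Capn11.

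**Figure D3:**
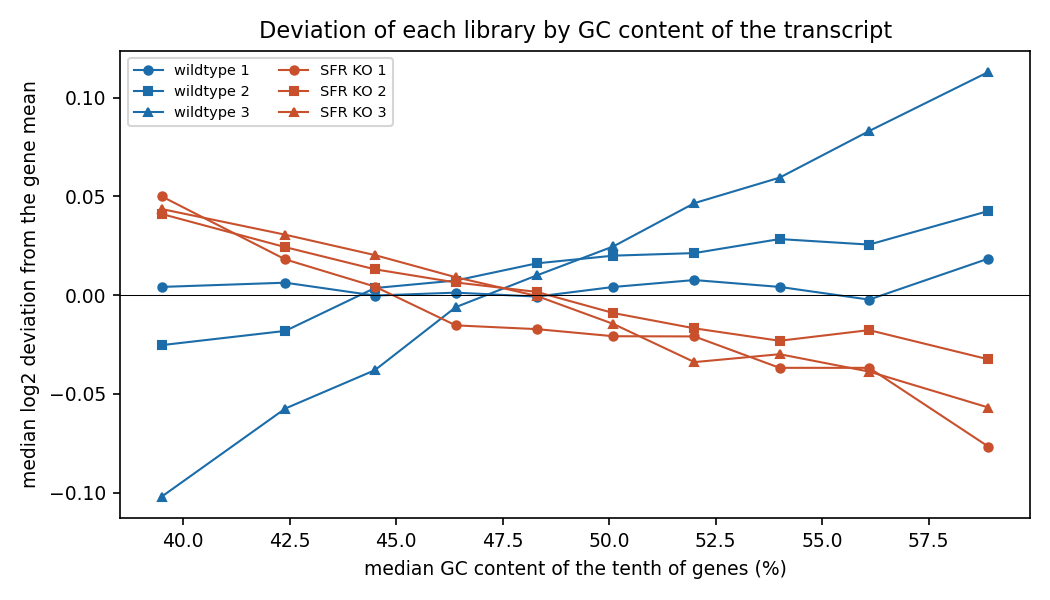
Median log2 deviation of each library from the gene mean (vertical axis) by median GC content in percent of each of 10 bins of protein-coding genes (horizontal axis), 1 line per library. In the bin richest in GC, wildtype 1, 2 and 3 lie at 0.0185, 0.0426 and 0.113 and the SFR KO libraries lie between -0.0767 and -0.0325.

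The next question was whether groups of genes moved together. Genes of the light zone programme, where B cells test their receptors and receive T cell help, had a median log2 difference of -0.17, and of -0.09 after GC correction. Camera's adjusted p was 0.000269 with a preset correlation of 0.01 (0.00207 after GC correction), against an adjusted p = 0.358 with an estimated correlation. Of 26 members, 20 had fitted values below 0, 4 fell in the test over all genes, none rose, and 8 fell when adjusted over the list alone. The 4 were Myc, the activation marker Cd83 (log2 -0.27 ± 0.04, limma adjusted p = 0.0464), the activation-induced factor Egr1 (-0.42 ± 0.07, adjusted p = 0.0486) and the semaphorin gene Sema7a (-0.31 ± 0.05, adjusted p = 0.0479). Of the members, edgeR called 1, DESeq2 called 8 and 10 had an unadjusted p under 0.05. Over all 13562 tested genes these counts were 30, 491 and 2185, the rates beside which the member counts of each list are to be read. After GC correction the 4 kept 69.3% to 87.8% of their log2 difference but missed limma's threshold. Myc was then at -0.45 ± 0.08 (adjusted p = 0.0862), Cd83 at -0.22 ± 0.04 (0.101), Egr1 at -0.33 ± 0.08 (0.153) and Sema7a at -0.21 ± 0.05 (0.136). None of the 10 lists called at the preset correlation held with an estimated one. For the light zone list and the list of MYC targets the estimates were 0.00406 and 0.00342, below the preset 0.01. A higher correlation between members was therefore not why these 2 lists missed the threshold. Their unadjusted camera p rose from 2.45e-05 and 0.00696 to 0.0109 and 0.0463 although the correlation was lower. The preset and estimated settings thus differ in more than the correlation. Missing the threshold with an estimated correlation does not by itself show that the members of a list vary together. Fry called these 2 lists and no other (fry adjusted p = 0.0432 each). Genes of B cell receptor signalling had a median of -0.09 (camera adjusted p = 0.00121; adjusted p = 0.619 with an estimated correlation), and of -0.05 after GC correction (camera adjusted p = 0.00473). Of 24 members, Syk fell and Cd72, an inhibitor of that signalling, rose; adjusted over the list alone 6 fell and 1 rose, edgeR called 1 and DESeq2 called 5. After GC correction Syk was at -0.30 ± 0.05 and missed limma's threshold (adjusted p = 0.0651), while Cd72 was at 0.58 ± 0.08 (0.0281). Dark zone genes, for cells in division and mutation, had a median of 0.02 (camera adjusted p = 0.35). Limma and edgeR called 0 of 12 members, DESeq2 called 2, 3 had an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. Cxcr4, the receptor that places cells there, was at a log2 difference of 0.34 ± 0.06 with a limma adjusted p = 0.0555.

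Resting follicular B cell genes (median -0.28, camera adjusted p = 0.0287), marginal zone and B-1 cell genes (-0.20, 0.0491) and MYC targets with ribosome biogenesis genes (-0.08, 0.0287) were lower as lists. With an estimated correlation the adjusted p was 0.807, 0.756 and 0.619. Limma and edgeR called 0 of their 16, 15 and 20 members, DESeq2 called 1, 3 and 1, and 7, 5 and 6 had an unadjusted p under 0.05. Adjusted over the list alone, 1 follicular gene rose, 1 marginal zone gene rose and 3 fell, and 0 MYC targets passed. The follicular gene was Cd38, an ectoenzyme, at a log2 difference of 0.56 ± 0.11 (limma adjusted p = 0.0659 over all genes), against the direction of its list. The sphingosine receptor gene S1pr3 of the marginal zone list stood at -0.42 ± 0.07 (adjusted p = 0.0522). Among follicular genes named after their values were seen, Fcer2a, the CD23 gene, had 5421.1, 6382 and 4275.1 normalized reads in wildtype 1, 2 and 3 and 6270.8, 2546.5 and 2150.4 in SFR KO 1, 2 and 3. The complement receptor gene Cr2, a member of the follicular and marginal zone lists, had 8897.7, 9265.3 and 7140.4 and then 7905.5, 4233.6 and 4854.2, so that SFR KO 1 lay within the wildtype range for both genes. The follicular list missed the threshold without wildtype 1 (adjusted p = 0.191), SFR KO 2 (0.0969) or SFR KO 3 (0.114) and with DESeq2 (0.0897), and stood at 0.000194 without SFR KO 1. The marginal zone list missed it without wildtype 1 (0.208) or SFR KO 2 (0.283), after GC correction (0.0543) and after GC and length correction (0.0515). The MYC list missed it without wildtype 3 (0.0663) or SFR KO 2 (0.0625), after GC correction (0.162, with a median of -0.04), after GC and length correction (0.114) and with wildtype 1 as the sole wildtype library (0.233). With a minimum mean of 50 normalized reads all 3 lists missed it (0.0531 each).

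Glycolysis genes (median 0.06, camera adjusted p = 0.0404) and genes of cytosolic ribosomal proteins (0.05, 0.0195) were higher as lists. With an estimated correlation the adjusted p was 0.756 and 0.863. After GC correction the medians were 0.11 and 0.09, with a camera adjusted p = 6.4e-05 each at the preset correlation. With GC correction and an estimated correlation, 0 lists were called. Limma and edgeR called 0 of their 16 and 24 members, DESeq2 called 1 and 0, and 5 and 1 had an unadjusted p under 0.05. Adjusted over the list alone, 1 glycolysis gene rose and 0 ribosomal genes passed. Tpi1, the triosephosphate isomerase of glycolysis, stood at a log2 difference of 0.21 ± 0.05 (limma adjusted p = 0.102). The ribosomal list missed the threshold without wildtype 2 (adjusted p = 0.279) or SFR KO 1 (0.429) and with wildtype 1 as the sole wildtype library (0.155), and these values are uncertain because reads can be shared with pseudogenes. The glycolysis list missed it without wildtype 1 (0.0946), wildtype 2 (0.117), SFR KO 2 (0.0899) or SFR KO 3 (0.0613) and with wildtype 1 as the sole wildtype library (0.0678).

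Lists of markers of other cells and of RNA quality were among those called at the preset correlation. Transcripts of the mitochondrial genome had a median log2 difference of 0.50 (camera adjusted p = 5.47e-08; adjusted p = 0.619 with an estimated correlation), with all 10 tested members above 0. Both ribosomal RNAs rose, mt-Rnr2 by 1.41-fold (limma adjusted p = 0.0322) and mt-Rnr1 by 1.4-fold (adjusted p = 0.0486), and 8 members rose when adjusted over the list alone; edgeR called 1 member and DESeq2 called 3. After GC correction mt-Rnr2 was at a log2 difference of 0.35 ± 0.06 against 0.50 ± 0.07 before, and mt-Rnr1 at 0.35 ± 0.08 against 0.48 ± 0.08. Both then missed limma's threshold (adjusted p = 0.101 and 0.145). The mitochondrial share of reads was 1.511%, 2.12% and 1.533% in wildtype 1, 2 and 3 and 2.47%, 2.461% and 2.448% in SFR KO 1, 2 and 3. T cell marker genes were higher as a list (median 0.67, camera adjusted p = 0.000269; adjusted p = 0.756 with an estimated correlation). Limma and edgeR called 0 of 18, DESeq2 called 1, 8 had an unadjusted p under 0.05, and 1 rose when adjusted over the list alone. This was Il21, the cytokine of follicular helper T cells, at 5.63 ± 1.31 normalized reads in wildtype and 24.15 ± 10.91 in SFR KO libraries (limma adjusted p = 0.105 over all genes). The T cell list missed the threshold where wildtype 1 was the sole wildtype library (adjusted p = 0.518). Granulocyte genes were lower as a list (median -1.22, camera adjusted p = 0.021; adjusted p = 0.829 with an estimated correlation). Limma, edgeR and DESeq2 called 0 of 10, 0 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. S100a9, a neutrophil calcium-binding protein named after its values were seen, stood at 1892.5 normalized reads in wildtype 1 and between 123.7 and 583.3 in the other libraries. The granulocyte call was lost without wildtype 1 (adjusted p = 0.319) or SFR KO 2 (0.283) and with a minimum mean of 50 (0.0531).

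**Figure D4:**
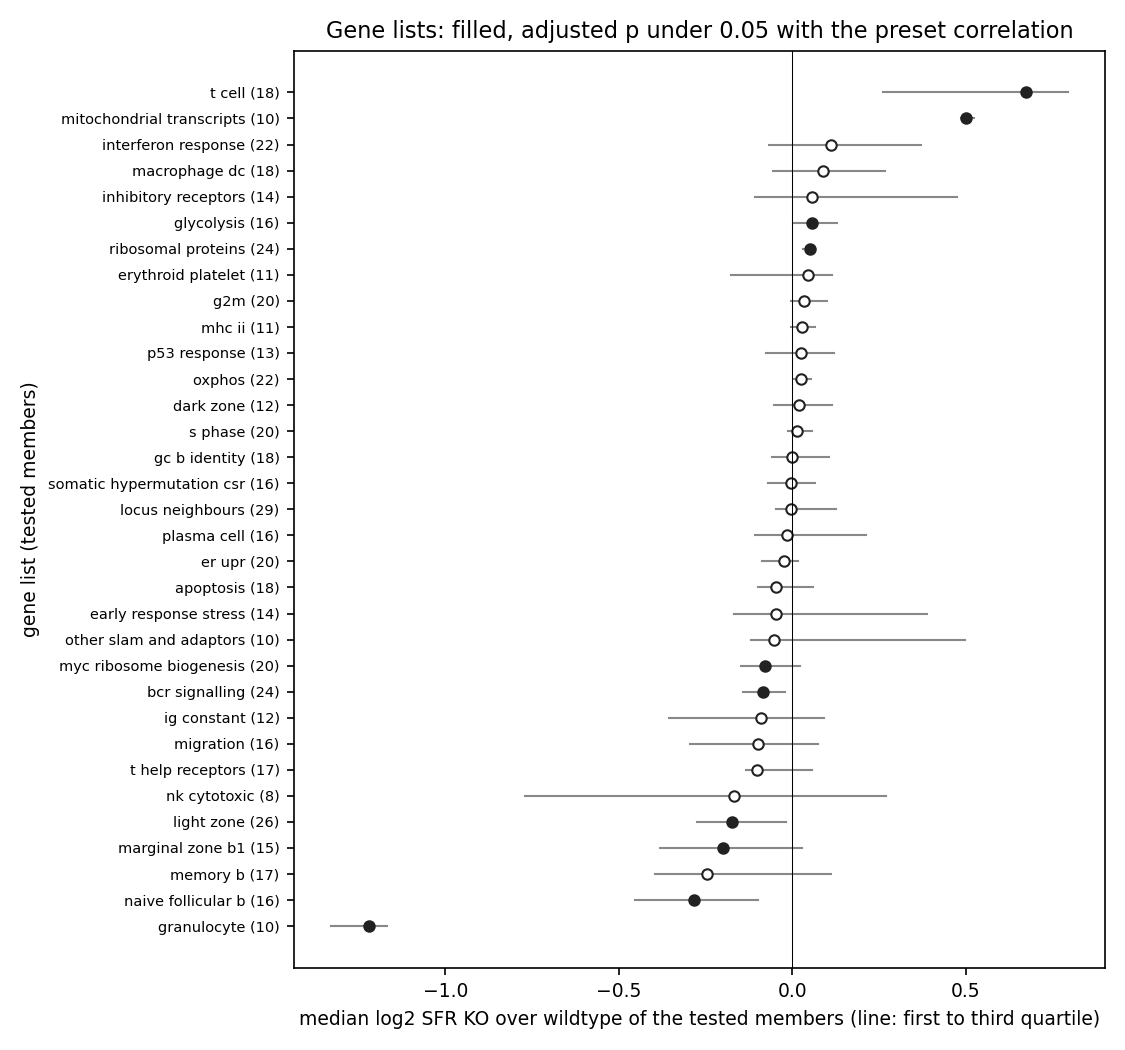
Median log2 difference of SFR KO over wildtype (horizontal axis; lines span the interquartile range of the tested members) of the 33 gene lists tested, ordered by median; filled points mark the 10 lists with a camera adjusted p under 0.05 at the preset correlation. The T cell list lies highest at 0.67 and the granulocyte list lowest at -1.22.

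The other 23 lists missed the threshold, with camera adjusted p-values from 0.0506 for G2 and M phase genes to 0.964 for immediate early genes. Among B cell states, adjusted p was 0.769 for germinal centre identity, 0.27 for memory and 0.35 for plasma cell genes. Adjusted over the list alone, 2 germinal centre genes rose and 1 fell, 2 memory genes rose and 3 fell, and 3 plasma cell genes rose, Eaf2 among them. Camera's adjusted p was 0.125 for receptors of T cell contact, 0.769 for MHC class II, 0.35 for inhibitory receptors, 0.35 for positioning receptors, 0.769 for antibody constant regions and 0.96 for neighbours of the deletion. Receptors and partners of the SLAM family outside the deletion gave 0.769. Among them Inpp5d, a phosphatase that SLAM receptors can recruit, was at a log2 difference of -0.14 ± 0.04 (limma adjusted p = 0.164). S phase genes gave 0.426, oxidative phosphorylation 0.203, apoptosis 0.548, p53 targets 0.769, hypermutation and repair 0.96, unfolded protein response 0.35 and interferon response 0.0755. Klf6 rose and Egr1 fell within the immediate early list, whose median was -0.05 and mean 0.09. Markers of NK cells gave 0.769, of macrophages and dendritic cells 0.809, and of erythroid cells and platelets 0.96. Of 11 stromal genes 3 were measured, and that list was not tested.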

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

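The alternatives with a GC correction and the fit with wildtype 1 as the sole wildtype library were chosen after the data were seen, the others before. No paired analysis was possible because the labels give no shared replicate number. Against 21 higher and 42 lower genes, the counts were 47 and 82 with no filter on low values (24646 genes tested) and 35 and 63 with a minimum mean of 50 (10755 tested). They were 11 and 19 with edgeR, 188 and 303 with DESeq2, 271 and 359 with sample weights and 55 and 106 with robust eBayes. They were 7 and 9 after GC correction, 9 and 12 after GC and length correction, and 4 and 7 with wildtype 1 as the sole wildtype library, which leaves 1 sample in that group. Leaving out 1 library gave 4 to 220 higher and 7 to 281 lower genes, the most without SFR KO 1 and the fewest without SFR KO 2. All 63 calls kept their sign under each of the 20 settings that tested them. The groups did not overlap for any called gene, so leaving out libraries or changing the pseudocount or filter could not have turned a sign. EdgeR called 30 of the 63, and DESeq2 called 60 with no adjusted p for the other 3. Beyond the numbers of genes tested or samples left, the cause was not tested. The 10 called lists became 6 with a minimum mean of 50, 0 with an estimated correlation, 0 with an estimated correlation after GC correction, 2 with fry and 5 to 15 without 1 library. The lists of light zone, B cell receptor signalling and mitochondrial genes kept their call in all 20 settings at the preset correlation. The count of 6 or 7 deleted genes called lower differed by Cd244a. Neighbours of the deletion went from 0 to 2 at an unadjusted p under 0.01 and to 0 to 1 without 1 library. Directions turned without wildtype 2 for genes that were never called. Over the fits without 1 library, the log2 difference ran from -0.15 to 0.0095 for Kdm5d, from -0.11 to 0.0056 for Ddx3y and from -0.031 to 0.59 for Vwf. With wildtype 1 as the sole wildtype library it was -0.57 for Vwf.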

Other observations

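Which tests were chosen after the result was seen: those on the deleted genes within the wildtype group, on GC content and on Iglv1; the counts over other splits of the libraries were fixed before. Antibody genes of the response to NP, which in this strain often joins the heavy chain segment Ighv1-72 with the lambda 1 light chain, varied between libraries of both genotypes. These genes were named after their values were seen, and reads of antibody segments can be shared between related segments. Iglv1 had 13352.5, 15364.2 and 7529.4 normalized reads in wildtype 1, 2 and 3 and 14452.1, 3723.4 and 3629.2 in SFR KO 1, 2 and 3 (log2 difference -0.99 ± 0.48, limma adjusted p = 0.354), and Ighv1-72 had 2979.5, 3121.3, 1691.2, 3144.3, 624 and 708. Ighg1, the constant region of IgG1, ranged from 876.6 in SFR KO 3 to 45893.1 in wildtype 1. Of 193 tested variable segments 1 was called, Ighv9-1, which fell from 327.4 ± 88.31 to 96.82 ± 18.22 normalized reads (log2 -1.73 ± 0.22, adjusted p = 0.0194), and 45 had an unadjusted p under 0.05. Ighg3 had a log2 difference of -1.33 ± 0.27 (adjusted p = 0.0654) and Ighg2c of 0.64 ± 0.16 (adjusted p = 0.11).

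As a hypothesis, the share of cells of the lambda 1 response to NP could differ between libraries of both genotypes. Over the 6 libraries, on the log2 scale and among 5 relations tested, Iglv1 rose with Ighv1-72 (Pearson's r = 0.994, exact permutation p = 0.00694, adjusted 0.00833; Spearman's rho 0.886, exact permutation p = 0.0333, adjusted 0.0416; r = 0.993 without SFR KO 2 and 3, the libraries farthest from the median). It also rose with genes that resting follicular B cells express as well: the CD23 gene Fcer2a (r = 0.988, rho 1; r = 0.969 without those libraries) and the complement receptor gene Cr2 (r = 0.966, rho 0.886, exact permutation p = 0.00833 and 0.0333, adjusted 0.00833 and 0.0416; r = 0.826 without them). For Fcer2a and for the lambda constant region Iglc1 (r = 0.999, rho 1; r = 0.999 without them) the exact permutation p was 0.00139 for r and 0.00278 for rho, the smallest that 6 libraries can give (adjusted 0.00348 and 0.00695). Iglv1 and Iglc1 are parts of the same lambda 1 light chain. Their relation had to be close whatever the share of cells responding to NP, and carries no weight for the hypothesis. Ighg1 gave r = 0.868 and rho 0.829 (exact permutation p = 0.00694 and 0.0583, adjusted 0.00833 and 0.0583; r = 0.93 without them), and with no measure of antigen binding no other cause was tested.

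The deleted genes were higher in wildtype 1 than in the other wildtype libraries. Over the 7 genes the median ratio of wildtype 2 to wildtype 1 was 0.52 (0.445 to 0.604) and of wildtype 3 to wildtype 1 it was 0.502 (0.335 to 0.534), while over 25 genes within 1 Mb outside the segment the medians were 1.03 and 1.05; none of 10000 random lists matched on expression had medians as low (lowest 0.801 and 0.832). This is what 1 deleted copy of the segment in wildtype 2 and 3 could give, a hypothesis found and tested on the same data, and the labels name no such genotype. Cells of another type in wildtype 1 stay open as a source, since 47 genes outside the segment were at least 1.5 times higher there than in both other wildtype libraries, among 8920 with a wildtype mean of at least 200. Of these 15 were granulocyte, erythroid or macrophage markers; S100a9 had 1892.5 against 309.8 and 219.4 normalized reads, although a sort for GFP is meant to remove such cells.

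The GC trend divided the calls outside the deletion. For the light zone list the median went from -0.17 to -0.09 after correction. Camera's adjusted p at the preset correlation was then 0.00207 (2.31e-06 to 0.00228 over the settings at that correlation). This test cannot decide whether the trend lowered the list, since it called up to 15 lists in splits that mixed the genotypes. Among the 55 calls, the trend as the whole cause is argued against gene by gene for 9. These stayed under the threshold after its removal, with at least 88.7% of their log2 change. The other 46 kept a median of 78.7% (55.2% to 110%), with a median absolute log2 change of 0.398 before and 0.332 after and a median standard error of 0.065 and 0.063; the change was smaller in 44 and larger in Saraf (named after its values were seen) and Nrep, and 9 of the 46 kept an unadjusted p that would have been called before, since the largest called p went from 0.000232 to 4.68e-05. As a set these 46 argue against the trend as the whole cause: the median change left, 0.332, exceeded the median standard error, 0.063. They were chosen as calls from the same data. Whether each of them differs apart from the trend stays open because none passed the threshold. Among them were the 4 called light zone genes with 69.3% to 87.8% of their change. With an estimated correlation the light zone list missed the threshold both before (camera adjusted p = 0.358) and after correction (0.345), which says nothing about the trend. The slope against GC content was 0.0474 ± 0.0509 per 10 percentage points in wildtype and -0.0475 ± 0.00622 in SFR KO libraries (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 can give), and a genotype effect on GC-rich genes was not tested. Most of the wildtype slope came from wildtype 3, at 0.105 against 0.00842 in wildtype 1 and 0.0287 in wildtype 2. Slopes were taken on each library's deviation from the gene mean over all libraries, so the group means are opposite by construction. The values therefore show the difference between the groups, -0.0948 for SFR KO minus wildtype. They do not show a trend of the SFR KO libraries on their own.

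The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 21 higher and 42 lower genes with limma, and the highest of the other splits 0 in either direction, so that 1 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 2185 genes and the highest other 1203, with SFR KO 1 beside wildtype 1 and 2. For gene lists the real split gave 10 and the highest other 15, with SFR KO 1 beside wildtype 1 and 3, and 3 of the 10 splits gave as many.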
